A study of Homo sapiens with 16 samples.

How the data were processed

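Chromatin accessibility was measured by ATAC-seq, in which the Tn5 transposase inserts adapters into open chromatin, in DND41 and MOLT4 cells, both established human T-cell acute lymphoblastic leukaemia lines. There were 16 libraries in 8 groups of 2, with each line given DMSO or 100 nM ACBI-1 for 3 h or 24 h. The labels do not say whether the 2 libraries of a group came from separate cultures, so p-values measure only the spread between these libraries, which may be technical. Groups were taken from the sample titles. In 8 of the 16 samples the cell line field of the labels named the other line. In all 16 libraries the line code inside the deposited peak names matched the title, and the library sharing most regions came from the line of the title, against 8 of 16 for the field.

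The submitters' processing notes name Bowtie2, Picard, SAMtools and MACS2 2.1.1.2016030 and the hg19 build, without roles or settings. Each deposited file was a peak list of 1 library, with 4 columns holding the chromosome, start, end and name of each peak, and peaks within a library did not overlap. The deposited values used here were positions only. Peak heights, summits, fold enrichments, p-values, q-values and read totals were not analysed here, so read depth is unknown and no counting interval was given. The peak names carried the tag p03 in the 8 libraries of 24 h and p04 in the 8 libraries of 3 h. The meaning of the tag is not given in the sources used here, so time, preparation and any calling setting behind the tag cannot be told apart.

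Peaks on chromosomes 1 to 22 and X were kept, and no filter for repeated or poorly mapped sequence was applied here. Peaks of any library that shared at least 1 base were merged into regions, and each region was scored as with or without a peak in each library. Coordinates are hg19, counted from 1. The gene table at hand is on another build, so no gene was assigned to a region. The planned tests of promoter share, gene lists, single genes, motifs and implied background were not run, nor were the planned settings that need q-values or summits. The rule for named items, fixed before the data were examined, then gave the 5 strongest lost and the 5 strongest gained regions by position. Strength was to be fold enrichment and was replaced by the mean percentile of peak width within each list, over the libraries of the arm with the peak.

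Treatment was tested with a two-sided exact permutation test that exchanged the labels only within each line and time, over 4 strata and 1296 exchanges, with a smallest possible p of 0.00154. Within 1 line or 1 time the smallest possible p is 0.0556, and within 1 line at 1 time it is 0.333. Regions were tested where their numbers of peaks per stratum allowed a p of 0.05 or less, with Benjamini-Hochberg adjustment, and called at an adjusted p under 0.05. Cell lines were compared in the same way within each time and treatment. The differences of the treatment effect between times or lines were tested by exchanging time or line labels. A shift between times or lines shared by both arms widens the spread of that test, so it can miss such a difference.

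Some analyses were chosen after the data were seen. Regions found in at least 4 libraries and no more than 12.5 kb apart were joined into loci of at least 3 regions, and the number of regions with a peak per locus and library was tested in the same way. Reference sites for a library were regions with a peak in both DMSO libraries of its line at the other time, so that no library helped to choose the sites it was scored on. Libraries of 3 h and 24 h were thus scored on different sites, so a difference between times at these sites may come from the choice of sites. Sites were called shared when both DMSO libraries of the other line at that time also had a peak, and line-restricted when neither did. They were divided into narrow, middle and broad tertiles by DMSO peak width. The share of sites with a peak was compared between arms for 27 classes, and differences between classes for 11 contrasts, each family with Benjamini-Hochberg adjustment. Chromosome shares were tested over 23 chromosomes. Adjustment by direction, the ratio of line-restricted to shared sites and the overlap expected within 20 width bins were also added after the data were seen.

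Alternatives tried were all sequences, each library left out, a replicate block, other region filters and an unstratified test. Those added after seeing the data were a common minimum peak width of 170 bp, equal list lengths of the 26145 widest peaks, peaks supported by another library, regions built from midpoints within 250 bp, and for loci a 5 kb gap or at least 5 regions. The region test was tested on simulated presence calls for 131357 regions with the occupancy of the real ones. With 2000 regions changed from a probability of 0.95 to 0.05 or the reverse, 82.3% were called, with 1 false call and no call in the wrong direction. With 200 such regions, or 2000 changed between 0.9 and 0.3, the test called 0. Unchanged regions had the same probability in both arms, and equal numbers of changed regions rose and fell. A drop over whole libraries, as lower depth would give, was not simulated, so the false calls do not cover it. The smallest possible p means that regions can only be called together in large sets, of at least 250 among the 8082 tested for treatment. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used.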

Results

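The series compared open chromatin in DND41 and MOLT4 cells after DMSO or 100 nM ACBI-1, a PROTAC that directs the SWI/SNF ATPases SMARCA2 and SMARCA4, and the PBRM1 subunit, to degradation. SWI/SNF complexes move nucleosomes and keep many regulatory sites accessible. Cells were taken at 3 h and 24 h, with 2 libraries in each of the 8 groups. The lists held 26145 to 46712 peaks per library on chromosomes 1 to 22 and X. Read depth is unknown, so a peak missing from a list may lie below the detection limit of that library. Merging gave 131357 regions, of which 12037 had a peak in all 16 libraries and 66967 in 1 library only.

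The first comparison was between ACBI-1 and DMSO over the whole genome. ACBI-1 libraries had fewer peaks in both lines and at both times. They held 30710 ± 2522 peaks (SD, n = 8) and DMSO libraries 42551 ± 3102 (SD, n = 8), and the highest ACBI-1 library, at 33870, lay below the lowest DMSO library, at 39117. Stratified by line and time, peak number fell by 27.9%, a log2 ratio of -0.47 (SE 0.06), with an exact permutation p of 0.00154, the smallest the design can give. In DND41 the number went from 42533 ± 4822 to 28763 ± 3702 at 3 h and from 44698 ± 2848 to 32629 ± 730 at 24 h (SD, n = 2 each). In MOLT4 it went from 43575 ± 2155 to 30139 ± 935 at 3 h and from 39398 ± 397 to 31311 ± 3620 at 24 h (SD, n = 2 each).

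**Figure D1:**
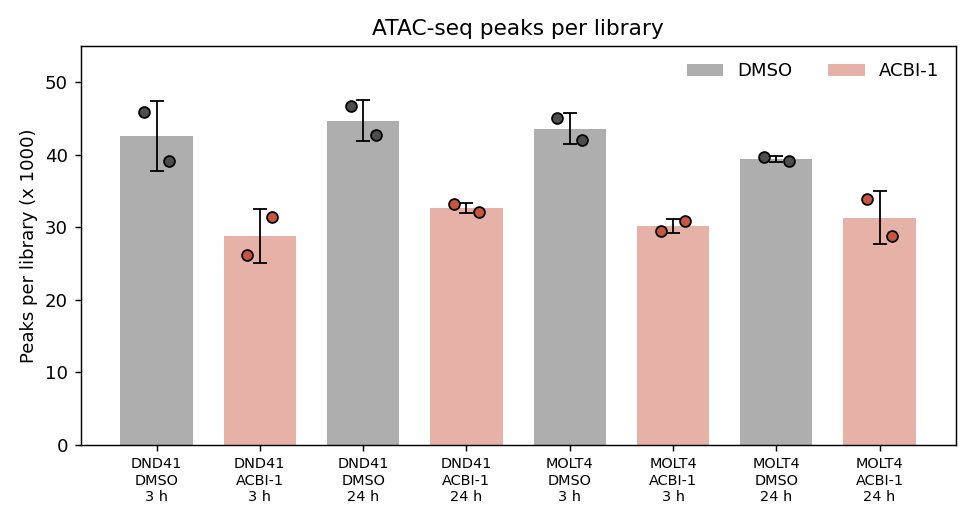
Peaks per library on the y axis (scale x 1000) for the 8 groups of line, treatment and time. Bars are means, error bars SD and points the 2 libraries of a group, and all 8 ACBI-1 libraries, at 26145 to 33870 peaks, lie below all 8 DMSO libraries, at 39117 to 46712.

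The genome covered by peaks fell with their number, from 18.96 ± 2.27 Mb in DMSO to 13.9 ± 1.69 Mb in ACBI-1 libraries (SD, n = 8 each). The log2 ratio was -0.45 (SE 0.08), with an exact permutation p of 0.00154. Median peak width was 356 ± 54.3 bp in DMSO and 360 ± 23.8 bp in ACBI-1 libraries (SD, n = 8 each), a difference not larger than the spread (exact permutation p = 0.673). That mean joins opposite directions, 11.4% at 3 h and -6.85% at 24 h (exact permutation p = 0.167 for both). The 24 h value came from MOLT4, at -13.2%, with -0.0052% in DND41. At 3 h the values were 13.0% in DND41 and 9.84% in MOLT4. The difference between times was -0.26 on the log2 scale (SE 0.10; exact permutation p = 0.103). Peaks in regions found in at least 1 other library fell by 29.7% (exact permutation p = 0.00154). The shortest peak of a list was longer with ACBI-1, 156 ± 11.8 bp against 146 ± 14.0 bp (SD, n = 8 each; exact permutation p = 0.00617).

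Peak number changed by -31.6% at 3 h and -23.9% at 24 h, and by -29.7% in DND41 and -26.0% in MOLT4. Each of these 4 values had an exact permutation p of 0.0556, the smallest that 1 time or 1 line allows. The difference between times was 0.15 on the log2 scale (SE 0.12; exact permutation p = 0.213). The difference between lines was 0.08 on the log2 scale (SE 0.12; exact permutation p = 0.517). Neither was larger than the spread, which does not show that the effects were equal.

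Regions with a peak in DMSO and none in ACBI-1 libraries far outnumbered the reverse in each line and time. In DND41 at 3 h, 6610 regions had a peak in both DMSO and in neither ACBI-1 library, 20.9% of the 31671 regions found in both DMSO libraries, and 233 showed the reverse. At 24 h in DND41 there were 7860, or 27.1%, against 1054. In MOLT4 there were 7693, or 22.2%, against 331 at 3 h, and 8382, or 27.7%, against 916 at 24 h. Pairing 1 DMSO with 1 ACBI-1 library on each side gave at most 1745 such regions in DND41 at 3 h, 939 in DND41 at 24 h, and 777 in MOLT4 at either time. The regions lost with ACBI-1 exceeded these baselines, whereas those gained lay below them at 3 h and only slightly above them at 24 h.

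**Figure D2:**
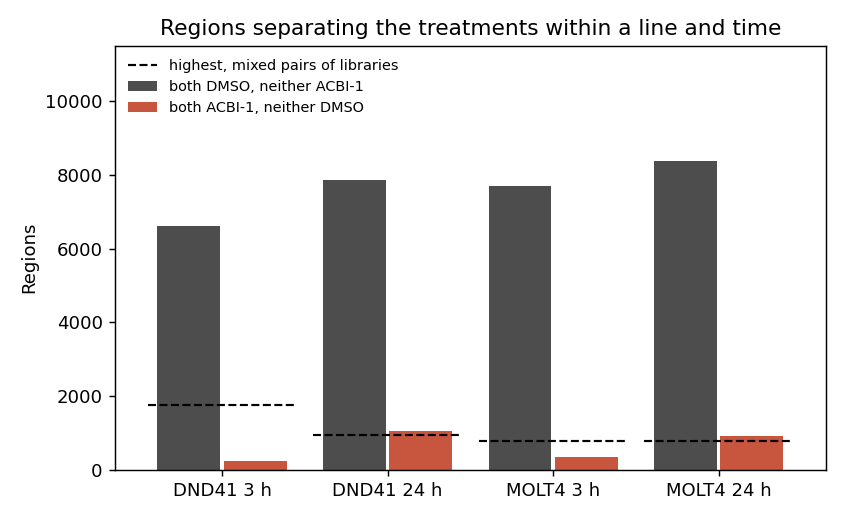
Number of regions on the y axis, for each line and time on the x axis, with a peak in both DMSO and neither ACBI-1 library (grey) or the reverse (red). Dashed lines give the highest count when each pair mixes the treatments, which the grey bars, at 6610 to 8382, exceed.

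Region by region over both lines and times, 8082 regions could be tested. Of these, 2251 were lost with ACBI-1 and 9 gained at an adjusted p under 0.05 in the exact permutation test, and 209 had a peak in all 8 DMSO and no ACBI-1 library. Lost regions had a median DMSO peak width of 307 bp, against 722 bp for regions found in all 16 libraries, which by construction cannot be called. The median width over all peaks of a DMSO list was 356 ± 54.3 bp (SD, n = 8). Tested regions that were not called were not compared. The lost count was at the edge of the adjustment. It was 0 without either 24 h ACBI-1 library of either line, without replicate 1 of DND41 DMSO or DND41 ACBI-1 at 3 h, and without replicate 2 of MOLT4 DMSO at 3 h, and it was 898 to 1110 without any of the other 9 libraries. Adjusted by direction, 3898 were lost among the regions lower with ACBI-1 and 0 gained among the 982 higher (exact permutation test), where at least 31 at the smallest p would be needed for any call and 36 had an unadjusted p under 0.05. That split uses the sign of the change itself, so its counts are no separate support for loss.

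The strongest lost region by DMSO peak width lay on chromosome 1 from 1148200 to 1149358 (hg19). It had a peak of 835 ± 174 bp (SD, n = 7) in 7 of 8 DMSO and in 0 of 8 ACBI-1 libraries (exact permutation test, adjusted p = 0.0442). The next were on chromosome 1 from 59407090 to 59407995 and from 9473095 to 9474147, each in all 4 DMSO libraries of both lines, in 2 of 4 ACBI-1 libraries of DND41 and in 0 of 4 of MOLT4. Those on chromosome 10 from 100027660 to 100028627 and chromosome 11 from 85862313 to 85863378 were in 8 DMSO and 2 ACBI-1 libraries. On chromosome 10 the peak was 657 ± 151 bp (SD, n = 8) with DMSO and 248 ± 54.4 bp (SD, n = 2) with ACBI-1. Among the 209 regions found in all DMSO and no ACBI-1 libraries, the broadest, picked after the values were seen, were on chromosome 9 from 137295536 to 137296237, chromosome 11 from 7597066 to 7597782 and chromosome 21 from 46506804 to 46507734, with DMSO peaks of 507 ± 99.2, 485 ± 157 and 472 ± 156 bp (SD, n = 8 each).

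The 5 strongest gained regions had narrower peaks. The region on chromosome 21 from 10085043 to 10086132 had a peak in all 8 ACBI-1 and no DMSO libraries, of 367 ± 209 bp (SD, n = 8). It was the only region of this kind, and whether it lies in repeated or poorly mapped sequence was not examined. The region on chromosome 9 from 100836580 to 100837313 was in 6 ACBI-1 and 0 DMSO libraries. Those on chromosome 1 from 69284950 to 69285349 and from 201330603 to 201331167, and on chromosome 12 from 3384549 to 3385037, were in 7 ACBI-1 libraries and 1 DMSO library.

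Which sites lacked a peak was then asked with reference sites chosen in libraries other than those scored. DMSO libraries had a peak at 87.9 ± 4.48% of the reference sites of their line and ACBI-1 libraries at 67.0 ± 8.54% (SD, n = 8 each; exact permutation p = 0.00154). Broad sites were mostly kept. ACBI-1 libraries had a peak at 95.5 ± 2.35% of the broad tertile, against 99.5 ± 0.272% with DMSO. In the narrow tertile they had a peak at 37.4 ± 10.1%, against 70.8 ± 10.6% with DMSO. The change in the narrow tertile minus that in the broad tertile was -29.4 percentage points (exact permutation p = 0.00154, adjusted 0.00243), in all 16 comparisons of an ACBI-1 with a DMSO library.

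Sites with a peak in 1 line only lost their peak call more often than sites shared by both lines, but in the narrow tertile this depended on the scale. Shared sites were found in 94.2 ± 2.68% with DMSO and 78.6 ± 7.63% with ACBI-1, and line-restricted sites in 72.7 ± 10.3% and 38.6 ± 11.6% (SD, n = 8 each). The difference of differences was -18.6 percentage points (exact permutation p = 0.00154, adjusted 0.00243). By tertile it was -11.9 points for broad and -16.0 points for middle sites (exact permutation p = 0.00154, adjusted 0.00243 for both), and -2.96 points for narrow sites, in 10 of 16 comparisons (exact permutation p = 0.230, adjusted 0.281). That value averages -1.06 points at 3 h and 7.01 at 24 h in DND41 and -13.0 and -4.75 in MOLT4, with a test between lines at an exact permutation p of 0.00154, adjusted 0.0725. As a ratio, ACBI-1 libraries had a peak at 0.42 of the DMSO percent for line-restricted and 0.587 for shared narrow sites. The log2 ratio of restricted to shared narrow sites changed by -0.54 (exact permutation p = 0.00154), at -0.36 and -0.24 in DND41 and -0.55 and -0.99 in MOLT4 at 3 h and 24 h. Line-restricted sites were narrower, and at matched width the difference of differences was -6.84 points (exact permutation p = 0.00309). At that width DMSO libraries still had a peak at 72.7% of line-restricted and 84.8% of shared sites. Matching by width thus did not make the sites equally easy to detect, and this value does not separate loss from weaker detection. The difference of differences at matched width was -3.08 points in DND41 (exact permutation p = 0.111) and -10.6 in MOLT4 (exact permutation p = 0.0556, the smallest 1 line allows). Sites in clusters of 5 or more were kept to 68.5 ± 4.96% and isolated sites to 66.9 ± 9.30% with ACBI-1, with a difference of differences of -0.75 points that was not larger than the spread (exact permutation p = 0.287).

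**Figure D3:**
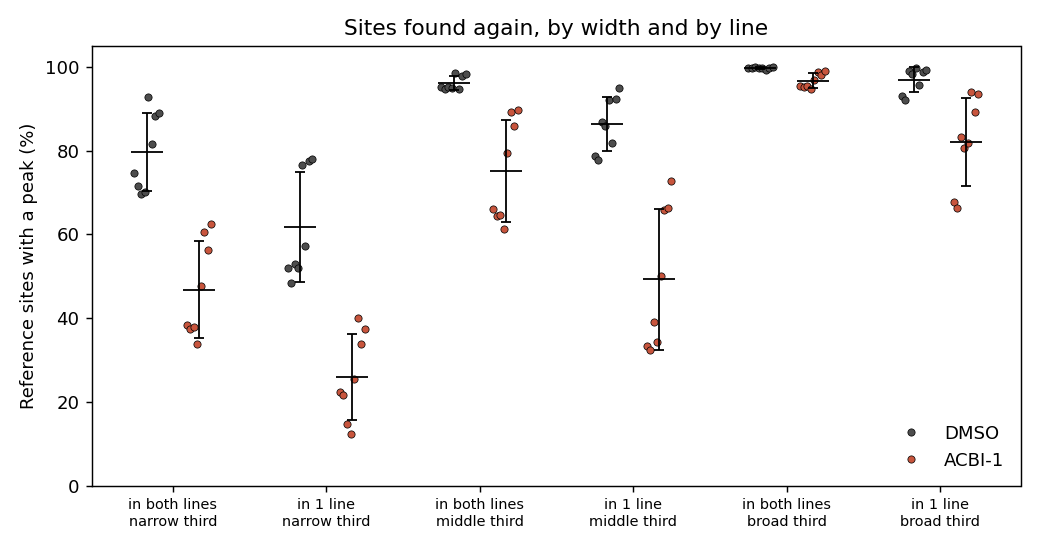
Percent of reference sites with a peak on the y axis, by width tertile and by whether the site was open in both lines or in 1. Points are libraries, horizontal marks means and error bars SD (n = 8 per arm), and with ACBI-1 the means run from 26.0% for narrow sites of 1 line to 96.7% for broad sites of both lines.

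The sites absent in the lines, and at the times, overlapped. Of 18483 regions with a peak in all 8 DMSO libraries, 763 had none in the 4 ACBI-1 libraries of DND41 and 758 none in those of MOLT4. In common were 209, where independent sets would share 31.3, and 97.6 when independent only within 20 bins of DMSO peak width. Split by time, 284 had no ACBI-1 peak at 3 h and 1594 none at 24 h, and the 209 in common compare with 24.5 for independent sets and 82.5 within width bins. The overlap therefore came in part from width, since narrow sites lost their peak first, and other features of weak sites were not matched. Without replicate 2 of DND41 ACBI-1 at 3 h, which removes a condition, the regions in common numbered 321. Of the regions lost in 1 line, libraries of the other line at that time had a peak at 47.3 ± 4.41% with DMSO and 17.5 ± 4.06% with ACBI-1 (SD, n = 8 each; exact permutation p = 0.00154). Regions kept in 1 line also fell in the other, from 87.4 ± 3.05% to 80.4 ± 4.09%, with the same p, so that p does not bear on overlap. The fall was larger for lost than for kept regions by -22.8 points (exact permutation p = 0.00154, adjusted 0.00243). This contrast was not matched for width.

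Regions absent at 3 h were mostly also absent at 24 h. Of 24799 regions in all 4 DMSO libraries of DND41, 2638 had no peak in either 3 h ACBI-1 library. Of these, 75.1% also had none in either 24 h library and 10.5% had a peak in both. In MOLT4, of 3107 such regions among 27066, 77.3% had none at 24 h and 8.34% had a peak in both. Absent at 24 h were 5475 of all 24799 regions in DND41 and 6723 of 27066 in MOLT4. Weak sites could be missed at both times in separate libraries. These counts were not compared at matched width, so persistence was not tested. At reference sites, ACBI-1 minus DMSO was -17.2 percentage points in each line at 3 h. At 24 h it was -23.1 points in DND41 and -26.4 in MOLT4. The difference for 24 h minus 3 h was -7.53 points (exact permutation p = 0.326), and that between lines -1.64 points (exact permutation p = 0.606). DMSO libraries differed between times too, with 90.2% at 3 h and 84.3% at 24 h in DND41, and 92.9 and 84.3% in MOLT4. The times were scored on different sites, each chosen in DMSO libraries of the other time. Sites scored at 24 h were narrower, with a narrow tertile up to 289.5 bp against 388.5 bp at 3 h in DND41, and 299 against 408 bp in MOLT4. Time and choice of sites therefore cannot be told apart in these values. The DMSO difference also widens the spread of the test between times, so its p does not decide whether the loss differed.

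Fewer peaks were found at many loci when lists were taken as deposited. Counts at loci are of regions with a peak, among regions found in at least 4 libraries, and not of all single peaks. Of 1845 loci tested, 1058 had fewer peaks with ACBI-1 and 1 had more at an adjusted p under 0.05 in the exact permutation test, and the number was 682 without replicate 1 of DND41 DMSO at 3 h. It was 625 with a common minimum peak width, 282 for loci of at least 5 regions, 197 with a 5 kb gap, and 0 with lists of equal length. The loci named here were picked by hand after their values were seen, from among the 10 largest differences. On chromosome 14 from 106538988 to 106692030, a locus of 21 regions had 15.5 ± 1.93 with a peak in DMSO and 10.8 ± 2.43 in ACBI-1 libraries (SD, n = 8 each; exact permutation test, adjusted p = 0.0183). A locus on chromosome 10 from 80853443 to 80907888 went from 6.88 ± 1.46 to 2.75 ± 1.49 regions with a peak. A locus on chromosome 1 from 172596827 to 172648829 had 8.75 ± 0.50 with DMSO and 5.0 ± 2.94 with ACBI-1 in DND41, and 5.75 ± 0.50 and 2.0 ± 1.15 in MOLT4 (SD, n = 4 each). A locus on chromosome 6 from 160435262 to 160490509 went from 6.0 ± 0.756 to 2.5 ± 0.535, and 1 on chromosome 12 from 104850264 to 104892583 from 8.13 ± 0.354 to 4.75 ± 0.707 (SD, n = 8 each). The 1 locus with more peaks, on chromosome 11 from 118166439 to 118187936, had 2 of its 3 regions in each DMSO library and 2.75 ± 0.463 with ACBI-1 (SD, n = 8).

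**Figure D4:**
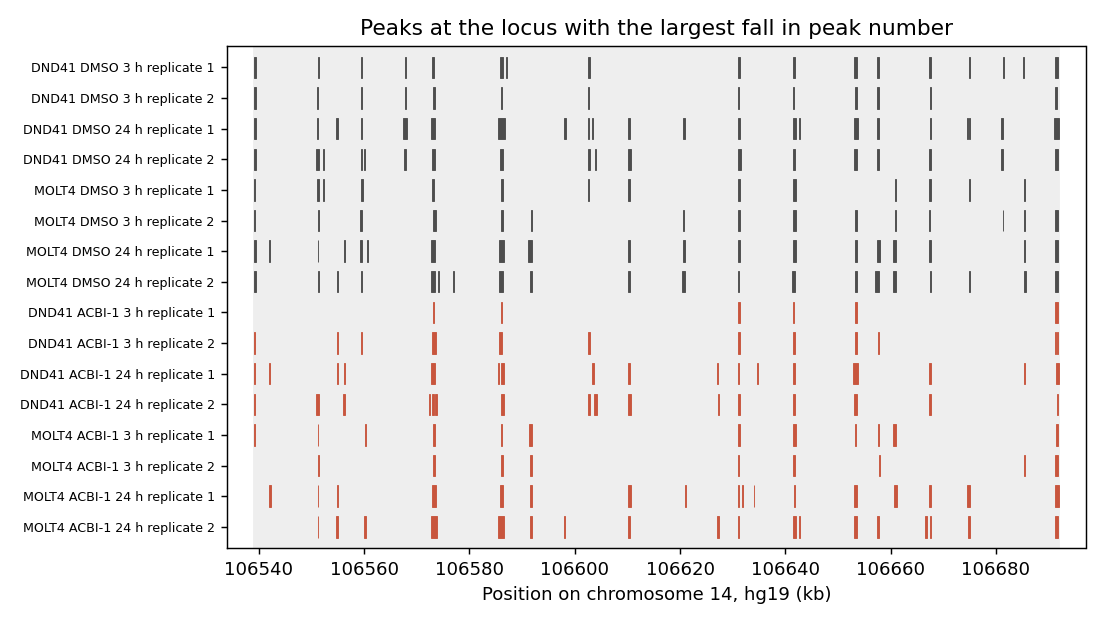
Peaks of the 16 libraries, 1 per row, along the locus on chromosome 14 (x axis, hg19 position in kb; shaded from 106538988 to 106692030). DMSO libraries (grey) had a peak in 15.5 of its 21 regions on average and ACBI-1 libraries (red) in 10.8.

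Chromosomes did not keep equal shares of the peaks. Chromosome 19 held 3.05 ± 0.436% of the peaks with DMSO and 3.60 ± 0.592% with ACBI-1 (SD, n = 8 each; exact permutation p = 0.00154, adjusted 0.0071), and the share was higher at both times. Chromosome 7 rose from 5.89 ± 0.159% to 6.19 ± 0.351% (exact permutation test, adjusted p = 0.0355). Chromosomes 2, 5, 10 and X fell, with differences of -0.359, -0.288, -0.245 and -0.249 percentage points, each with an adjusted p of 0.0071 in the exact permutation test. With lists of equal length the difference for chromosome 19 was 0.0765 points (exact permutation p = 0.378).

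The lines themselves differed at many regions. Of 11709 regions tested, 4783 were found more often in MOLT4 and 2731 more often in DND41 at an adjusted p under 0.05 in the exact permutation test, 1241 of all regions were in all 8 MOLT4 and no DND41 libraries, and 382 the reverse. A locus on chromosome 21 from 36335067 to 36423981 had 14.3 ± 0.957 regions with a peak in MOLT4 and 5.5 ± 1.73 in DND41 with DMSO (SD, n = 4 each). A locus on chromosome 7 from 38370464 to 38408132 had 10.5 ± 0.577 in DND41 and 3 in each MOLT4 library with DMSO (SD, n = 4). These 2 loci were also picked after their values were seen. Between times, 0 of 3762 regions were called in the exact permutation test, with 290 higher at 24 h and 299 higher at 3 h at an unadjusted p under 0.05. Any call there would need at least 117 regions at the smallest possible p, so 0 calls do not show that no region differed.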

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

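The tests at matched width, within 1 time or line, on the ratio scale, of gained regions between times and lines, and of gained regions at unadjusted p were chosen after the results were seen, as were the site classes and loci. Of 47 tests of whether the treatment effect differed between times or lines, 9 had an exact p under 0.05, where chance would give 2.35, and 0 had an adjusted p under 0.05. A lone difference among these tests could not have passed, since the lowest adjusted p that 1 of them can reach alone is 0.0725. The change with ACBI-1 at line-restricted minus that at shared narrow sites was -7.05 percentage points at 3 h and 1.13 at 24 h, a difference of 8.18, and 2.98 in DND41 and -8.89 in MOLT4, a difference of -11.9. As a log2 ratio it was -0.30 in DND41 and -0.77 in MOLT4, a difference of -0.47, so the lines agreed in direction on that scale. For sites lost against sites kept in the other line it was -16.2 points at 3 h and -29.4 at 24 h, a difference of -13.1. For regions gained at the other time, ACBI-1 minus DMSO libraries was 16.4 points higher at 24 h than at 3 h, and for regions gained in the other line 9.99 points higher. In all these contrasts between times, libraries of 3 h and 24 h were scored on different sites. For broad sites in clusters of 5 or more against isolated broad sites, MOLT4 minus DND41 was 1.16 points. For chromosome 19 against the other chromosomes, MOLT4 minus DND41 was 3.42 points over all sites and 0.829 points over broad sites.

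The fewer peaks of the ACBI-1 libraries could come from sites that closed or from a shallower or less enriched set of libraries. A common minimum peak width of 170 bp left the log2 ratio at -0.40 (exact permutation p = 0.00154), against a longer shortest peak as the whole cause. Depth stays open. The difference of differences of -11.9 points at broad sites had been set in advance as evidence against it, but that bound was wrong: line-restricted sites were narrower within that tertile (755 against 860 bp) and were missed more often in all 8 DMSO libraries too, so a shallower library would also lose them first. Lower depth would also give the loss of narrow sites. It would not give regions gained at 3 h that recur at 24 h, but such recurrence was not established. At regions gained at the other time, ACBI-1 minus DMSO was 9.50 points in the 24 h libraries and -6.94 points in the 3 h libraries. The exact permutation p at 24 h was 0.0556, the smallest possible, so that test cannot pass the threshold. No height or read total decides whether depth was lower. Of 100 splits of the libraries within strata, only the real one gave as many as 2251 lost regions or 1058 loci with fewer peaks (highest other 0 for both, as calls come only in large sets). At an unadjusted p under 0.05 the real split gave 4584 regions and 1199 loci and the highest other split 1603 and 511, so chance is unlikely for both. It is not excluded, since 100 of the 648 possible splits were drawn and they measure only the spread between these libraries.

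Whether the gained regions are library noise stays open. At regions gained at the other time, ACBI-1 minus DMSO was 9.50 points in the 24 h libraries (exact permutation p = 0.0556, the smallest possible) and -6.94 points in the 3 h libraries (exact permutation p = 0.111), so the mean of 1.28 points (exact permutation p = 0.727) averages opposite directions and decides nothing. With equal list lengths by width the mean difference was 18.6 points (exact permutation p = 0.00154), where 33.2 to 44.0% of each DMSO list and 0 to 22.8% of each ACBI-1 list was left out. Of 100 splits, only the real one called as many as 9 regions in its smaller direction (highest other 0), but those calls rest on adjustment together with the lost regions. At an unadjusted p under 0.05 the real split gave 36 and 9 of the 100 splits gave as many, up to 87, so chance cannot be excluded.

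Over both times together, broader sites did not account for the whole of the larger share of peaks on chromosome 19: its sites were kept more than the others by 2.85 points in the broad tertile (exact permutation p = 0.00772) and by 9.06 points at matched width (exact permutation p = 0.00309). At 24 h the values were 5.22 and 14.5 points (exact permutation p = 0.0556 for both). At 3 h they were 0.48 and 3.65 points (exact permutation p = 0.278 and 0.111). The difference between times had an exact permutation p of 0.0556 and 0.343. At matched width that p does not decide, since the DMSO difference itself differed between the times, which were scored on different sites. It went from -5.10 to 7.16 points in DND41 and from -5.38 to 6.75 in MOLT4. The share rose by 0.602 points at 3 h and 0.50 at 24 h, so at 3 h broader sites stay open. With equal list lengths by width the share no longer differed, at 0.0765 points, so the difference depends on that setting. A hypothesis is that sites kept without SWI/SNF are common on this chromosome. It was not tested, since no annotation of the build was used, and depth stays open here too.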

How the results depend on the processing

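The common minimum width, equal list length, midpoint, supported-peak and locus settings, and the results on loci, site classes and chromosome 19, were chosen after seeing the data. Peak number, covered length, the 2 contrasts of line-restricted with shared sites and the regions lost in the other line kept their direction and their side of the threshold under every setting run. Without each library in turn the log2 ratio of peak number ranged from -0.50 to -0.44 and that of covered length from -0.51 to -0.40. The log2 differences of the effect between times and between lines also stayed on their side of the threshold, but their size moved. Without each library they ranged from 0.088 to 0.22 for time and from 0.0096 to 0.14 for line. With supported peaks they were 0.049 and 0.0039. The number of lost regions moved under many settings. It went from 2251 to 0 when all regions in at least 2 and not all libraries were tested. It was 846 without strata, 713 with a common minimum width, 0 with equal list length and 859 with midpoint regions. Without each library it ranged from 0 to 1110. The 9 gained regions became 0, 1, 2, 0 and 2 under these 5 settings and 0 to 6 without each library. Fewer exchanges or more tests raise the adjusted p, which by construction can end all calls at once. The other causes were not tested. Regions differing between lines went from 7514 to 1623 with the first of these filters. Loci with fewer peaks went from 1058 to 625 with a common minimum width, 0 with equal list length, 197 with a 5 kb gap and 282 with at least 5 regions, and ranged from 682 to 1106 without each library. The 1 locus with more peaks became 0 under each of those 4 settings, and 0 to 3 without each library. Equal list length removes narrow peaks, where most loss lay.

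Regions absent in both lines rose from 209 to 1901 (567.7 for independent sets) with at least 3 of 4 DMSO and at most 1 of 4 ACBI-1 libraries, fell to 14 (1.26) with equal list length and ranged from 212 to 321 without each library. Between times the counts were 1906 (531), 14 (0.928) and 212 to 321. The 209 regions common to the times are by definition those common to the lines. Leaving out a library removes a condition, which favours a higher count, so that range is no check of the overlap. The chromosome 19 difference was 0.0765 points with equal list length. Regions gained at the other time differed by 18.6 points with equal list length (exact permutation p = 0.00154) and by -2.08 to 3.71 points without each library, and those gained in the other line by 20.2 points and -1.58 to 1.88 points. That setting left out on average 38.3% of the peaks of a DMSO list and 14.3% of those of an ACBI-1 list, the narrowest of each, in all DMSO and 7 of 8 ACBI-1 lists. The cause of these 2 changes was not tested.

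Same-numbered libraries did not deviate together, with correlations across regions of -0.04, 0.0009, -0.0033 and -0.0021 in the 4 strata. The replicate block, over 8 pairs, left peak number at -0.47 and covered length at -0.45 (exact permutation p = 0.00781 for both), and gave 2260 lost and 10 gained regions, 876 loci with fewer peaks and 1 with more. Settings that need q-values, summits, gene positions or sequence were not run: a stricter q threshold, equal length by q, summit-based regions, and all settings of the promoter, gene list, gene, motif and background results. Read depth limits every absence reported here.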

Other observations

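Over both treatments, peaks found in 1 library only were more numerous at 24 h than at 3 h, a log2 ratio of 1.23 (exact permutation p = 0.00463), and more numerous in DND41 than in MOLT4, at -0.75 for MOLT4 against DND41 (exact permutation p = 0.00617). In DMSO libraries alone the log2 ratio for time was 0.73 and was not shown to differ from 0 (exact permutation p = 0.167). They made up 20.5 ± 0.492% of the peaks in DND41 with ACBI-1 and 19.3 ± 2.99% with DMSO at 24 h, and 7.37 ± 0.194% and 8.54 ± 0.566% at 3 h (SD, n = 2 each). In MOLT4 at 24 h they made up 16.9 ± 5.06% with ACBI-1 and 7.31 ± 0.581% with DMSO, and at 3 h 5.05 ± 1.09% and 5.85 ± 2.03% (SD, n = 2 each). Covered length was also larger at 24 h, by 18.1% (exact permutation p = 0.00309), although the number of peaks was not shown to differ (exact permutation p = 0.509). Peaks in regions found in another library changed by -7.5% at 24 h against 3 h (exact permutation p = 0.0262). Median peak width was 13.4% larger (exact permutation p = 0.0185) and the shortest peak 15.4% longer (exact permutation p = 0.00154). Time cannot be told apart from preparation or from the tag in the peak names, and no biological explanation was tested.

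The cell lines differed at 7514 regions, and 1 of 100 splits of the libraries, the real one, gave as many (highest other 0, as calls come only in large sets). At an unadjusted p under 0.05 the real split gave 8211 regions and the highest other split 3767, so chance is unlikely. Here too, 100 of the 648 possible splits were drawn. Mitochondrial peaks numbered 5 to 10 per library, with a difference of 0.25 between ACBI-1 and DMSO libraries (exact permutation p = 0.667).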
